A study of Mus musculus with 2 samples.

How the data were processed

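The 2 libraries are 10x Genomics 3' v3 single-cell libraries of live lung cells that were CD45-positive and unlabelled by an intravenous CD45 antibody, from adult mice with a Gli1-driven, tamoxifen-inducible Cre and floxed Hhip, injected with oil or with tamoxifen, per the labels' protocols. The number, age, sex and strain background of the animals behind each library are not stated in the labels. The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 5.0.1 on the GRCm38 (mm10) mouse genome, per the submitters' processing notes. The annotation version is not given in the sources used here. The matrices were whole-number counts for 31053 genes, and no barcode had fewer than 500 UMIs, as found in the files. Gene positions came from GENCODE M21 on GRCm38, matched by gene identifier.

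Cells were kept with at least 300 genes, under 10% mitochondrial UMIs and no doublet call. Fewer than 300 genes were found in 1247 oil and 919 tamoxifen barcodes, and the mitochondrial limit was exceeded by 3302 (31.9%) and 2691 (20.7%). Scrublet was run on each library. In tamoxifen its automatic threshold marked 4.67% of 10138 barcodes (473), which were removed. In oil it marked 0.0589% of 6794, below the lower bound of 0.5%, so the 369 barcodes (5.43%) with the highest scores were removed instead, at a nominal 0.8% per 1000 barcodes. This left 6425 (62.1%) and 9665 (74.5%) of barcodes, with 49100071 and 74328607 UMIs and median mitochondrial shares of 3.14% and 3.09%. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 variable genes were chosen within each library, leaving out receptor segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes. Clusters came from 30 principal components, 15 neighbours and Leiden resolution 1 on both libraries together without batch correction, and lymphoid clusters other than B and plasma cells were clustered again. Random seeds were fixed at 1.

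Clusters were named from 30 marker sets, and are called after a cell type only in the sense of resembling it. A name needed at least 3 markers of the type, each found in 10% of the cluster's cells, and a mean log2 fold of 0.5 over the type's markers. Clusters led by markers of another type stayed unnamed. Clusters with a median UMI count under 1/3 of their library's needed 3 markers of the type among their 10 leading genes, a threshold set after the clusters were seen. A mean log2 fold of 2 over cycling markers made a cluster a cycling one. T cell clusters that reached the score of no subset were kept as T cells of no named subset.

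Shares of kept cells carry exact Clopper-Pearson 95% intervals, and log2 ratios of shares an interval from both binomials. Within each class of at least 100 cells per library, UMIs were summed per library and scaled by the total of the class in that library (CPM), with exact intervals for a ratio of Poisson counts. All intervals and limits cover counting error only. Where a count was 0, a ratio is given as a bound against 3 counts. With 1 library per group there is no replicate, and no test, p-value or number of changed genes is given. For 22 gene lists, the median log2 ratio of members with at least 20 UMIs was placed as a percentile among 10000 random lists of the same size matched on expression (drawn from the 100 genes nearest to each member). For medians, 0.5 UMI stood in place of 0. Of the listed genes, 3 (Cd244a, Ccl19 and Ccl21a) had no gene of that name in the matrices. Median-of-ratios scaling shifted all genes by -0.13 in CD8 T-like cells and by less than 0.1 in the other classes. Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs, leaving out shallower cells.

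The marker sets, gene lists, filters, alternative settings and the rule for named genes were fixed before the data were examined. The rule took, per class, genes with at least 30 UMIs and 50 CPM in the library where they were higher and at least a 2-fold difference, ranked by the interval bound nearest to no difference. It named up to 12 genes each way for the T, NK and ILC classes summed, alveolar macrophages, interstitial macrophages and B cells, and up to 4 each way for other classes. It left out receptor segments, mitochondrial, ribosomal and haemoglobin genes, genes without a proper name, and genes below 1/5 of their CPM in another class of the same library, which free RNA could give. It took 120 pairs of a gene and a class, and some genes, such as Setd5, were taken in several classes. Members of the lists are named as well. The comparison by sex of the cells, the Rosa26 region and genes on chromosomes 17 and 4 were chosen after their values were seen. A cell was called female with Xist UMIs and no UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, and male in the reverse case.

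The ratio and list steps were tested on simulated counts drawn from the real class means and depths. Each gene's count was an independent Poisson draw, the same model that the intervals assume. The test thus checks the computation only. Clumping of UMIs in few cells and joint variation of list members were not simulated, so calibration on the real data is not shown. In the T, NK and ILC classes (11769 genes) intervals covered the true ratio for 95.7% of genes, the naming rule took 0 of 50 genes changed 1.5-fold, 23 of 50 changed 2-fold, 50 of 50 changed 3-fold and 50 of 50 changed 4-fold, and no unchanged gene. In alveolar macrophages (11075 genes) coverage was 96.1%, with 0, 25, 50 and 50 genes taken and no unchanged gene. Of 400 simulated lists of 12 unchanged genes, 4.5% and 4.25% lay outside the middle 95% of random lists.

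In all, 24 alternatives were planned, covering doublet removal, the mitochondrial limit, the gene minimum, clustering, naming of cells, denominators, scaling, thinning and count minimums, and 11 were added after seeing the data, covering a mitochondrial limit of 25%, denominators without alveolar macrophages, the low-UMI cluster with Fabp1, cells of each sex and a fixed mix of T, NK and ILC classes. Immunoglobulin and T cell receptor repertoires and the raw reads were not analysed here. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.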

Results

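Gene expression was measured in 2 single-cell RNA sequencing libraries of immune cells sorted from adult mouse lung. The animals carried a tamoxifen-inducible Cre recombinase expressed from Gli1, a gene that marks Hedgehog-responsive mesenchymal cells, and floxed alleles of Hhip, which encodes a membrane protein that binds Hedgehog ligands and restrains the pathway. The control library came from oil-injected mice and the other from tamoxifen-injected mice, in which Hhip is deleted from cells that express Gli1. CD45 antibody was injected into the blood shortly before death, and live CD45-positive cells that had not taken up that antibody were sorted, which leaves out cells inside the vessels. The comparison asks what the loss of an extracellular Hedgehog inhibitor in the mesenchyme does to the resident immune cells of the lung, in particular to resident lymphocytes and their interferon-gamma. The oil library held 57704412 UMIs in 10342 barcodes and the tamoxifen library 83730550 UMIs in 12980 barcodes. After filtering, 6425 oil cells with a median of 6291 UMIs and 9665 tamoxifen cells with a median of 6297 UMIs remained. With 1 library per group there was no replicate and no test, so both values are given for each comparison, and their 95% intervals cover counting error only. Ratios are log2 values of tamoxifen over oil throughout.

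Hhip (ENSMUSG00000064325, GRCm38 chromosome 8, 79965851 to 80058006) was found at very low levels in both libraries, with 34 UMIs in kept oil cells and 29 in kept tamoxifen cells. Scaled by the library total (CPM), these were 0.692 and 0.390, a log2 ratio of -0.83 (-1.59 to -0.07). Most of them lay in the small population of fibroblast-like cells that passed the sort, where 26 UMIs (28.7 CPM) in oil and 28 UMIs (24.9 CPM) in tamoxifen gave -0.21 (-1.03 to 0.62). Over all barcodes the counts were 50 and 30, a log2 ratio of -1.27. Because the deletion occurs in mesenchyme and the libraries were sorted for CD45, these values do not measure recombination, and a 3' tag outside the deleted part, which the labels do not specify, checks nothing. Among pathway genes, the Hedgehog receptor Ptch1, itself a target of the pathway, was at 8.78 CPM in oil and 9.08 CPM in tamoxifen (0.05), and the pathway inhibitor Sufu was likewise close in both libraries (0.03). Smo, the signal-transducing receptor, was lower with tamoxifen, at 0.915 against 2.30 CPM (-1.33, -1.79 to -0.88). In fibroblast-like cells Smo had 37 UMIs in oil and 26 in tamoxifen (-0.82, -1.60 to -0.06). The value over all kept cells also depends on the mix of cells, which differed between the libraries. Gli1 had 8 UMIs in each library, and the ligand genes Shh, Ihh and Dhh had 0, 0 and 18 UMIs in oil and 2, 4 and 10 in tamoxifen. The Hedgehog list had 3 measured members in fibroblast-like cells, of which 1 was higher and 2 lower (median -0.21, at the 25.5th percentile of random lists matched on expression). Il7, which encodes a survival cytokine for T cells and innate lymphoid cells, had 26 UMIs in oil and 68 in tamoxifen (0.79, lower bound 0.12), of which 5 and 9 lay in fibroblast-like cells (0.54, -1.20 to 2.46).

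The lymphoid compartment differed in composition. ILC2-like cells, the innate lymphocytes that make IL-5 and IL-13, were 5.20% of oil cells (4.67 to 5.77) and 1.24% of tamoxifen cells (1.03 to 1.48), a log2 ratio of -2.07 (-2.36 to -1.77). NK or ILC1-like cells were also less frequent with tamoxifen, at 1.89% against 4.14% (-1.13, -1.40 to -0.86), as were Treg-like cells, at 1.26% against 2.21% (-0.81, -1.15 to -0.46). T cells of all subsets were more frequent, at 34.1% against 29.2% (0.22, 0.16 to 0.29), including CD4 T-like cells, with 306 cells in oil (4.76%) and 804 in tamoxifen (8.32%, 0.80, 0.62 to 0.99). CD8 T-like cells made up 3.13% and 2.83% (-0.14, -0.40 to 0.12), gamma-delta or type 17 T-like cells 1.95% and 1.42% (-0.46), T cells of no named subset 17.1% and 20.3% (0.24), B-like cells 2.83% and 3.49% (0.30, 0.04 to 0.56), and plasma-like cells 0.436% and 0.341%. T, NK and ILC classes summed were 38.5% of oil cells and 37.2% of tamoxifen cells (-0.05, -0.11 to 0.01), and 40.0% and 45.8% of cells other than alveolar macrophages (0.19, 0.14 to 0.25). The CD4 T-like difference came largely from 1 cluster that held 90 oil cells and 509 tamoxifen cells and was led by Cd200, Il17f, Lag3 and Il17a, while a cluster led by S1pr1 and Trat1 held 216 and 295. Since those leading genes are themselves among the genes that differed, the size of that cluster is not an independent finding. The gamma-delta or type 17 class leaves out that Il17a-led cluster. It also leaves out a cluster with 5830411N06Rik and Tcrg-C2 among its leading genes (122 oil and 325 tamoxifen cells), kept as T cells of no named subset. Its lower share is thus not that of all type 17 or gamma-delta T cells.

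The myeloid compartment differed mainly in its macrophages, monocytes and cDC2. Alveolar macrophage-like cells, the resident phagocytes of the airspaces, were 3.77% of oil cells (3.31 to 4.26) and 18.75% of tamoxifen cells (18.0 to 19.5), 4.98 times as frequent with tamoxifen (2.32, 2.13 to 2.50). Classical monocyte-like cells, in a cluster led by Ly6i, Cxcl9 and Chil1, were 1.40% and 4.33% (1.63, 1.30 to 1.95), and neutrophil-like cells 1.31% and 1.94% (0.57). Of the monocyte markers only Plac8 was among the leading genes of the monocyte-like cluster, beside Gpnmb, Inhba and Vegfa. No such class was found with each library clustered alone, so the name is uncertain. Interstitial macrophage-like cells were less frequent with tamoxifen, at 6.29% against 11.7% (-0.89, -1.04 to -0.75), and so were cDC2-like dendritic cells, at 4.22% against 10.3% (-1.28, -1.46 to -1.11). cDC1-like cells made up 7.80% and 6.43% (-0.28) and Ccr7-positive, migratory dendritic cells 2.16% and 1.57% (-0.46). A share depends on all other shares, and among kept cells other than alveolar macrophages the cDC1 ratio was -0.04, the interstitial macrophage ratio -0.65 and the CD4 T ratio 1.05. Fibroblast-like (2.57% and 1.95%), endothelial-like (2.09% and 1.08%), platelet-like (0.623% and 0.900%) and cycling cells (1.93% and 1.76%) were minor populations, and 12.4% of oil and 9.61% of tamoxifen cells stayed unnamed.

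Several of these shares depended on how cells were chosen. More oil than tamoxifen barcodes exceeded the mitochondrial limit, 31.9% against 20.7%, and 4 low-UMI clusters were kept out of any class by a threshold set after the clusters were seen. These were a cluster led by the alveolar macrophage gene Fabp1 (3.27% of oil and 4.13% of tamoxifen cells), a cluster of mixed endothelial and epithelial genes (4.62% and 3.01%), a lymphoid cluster led by Lncpint and Malt1 (3.86% and 1.48%) and a lymphoid cluster with B cell genes (0.140% and 0.393%). Counting the Fabp1 cluster as alveolar macrophages gave 7.03% and 22.9% (1.70). The alveolar macrophage ratio was 1.49 with each library clustered alone and 1.67 without doublet removal. The CD4 T ratio was 0.29 with each library clustered alone and 0.26 with cells named one by one, the interstitial macrophage ratio -1.32 and -0.54, the gamma-delta or type 17 ratio -1.22 and 0.12, and the Treg ratio -0.28 with cells named one by one. The CD8 T ratio was 0.20 without doublet removal and 0.14 with a mitochondrial limit of 25%. In the oil library 93 of 369 removed doublets were alveolar macrophage-like, beside 242 kept cells of that class. In the tamoxifen library they were 311 of 473, beside 1812 kept cells. The removed cells were named in the clustering without doublet removal and the kept cells in the main one. These counts thus do not give the part of the class that removal took. The way the doublet threshold was set also differed between the libraries.

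Both libraries contained female and male cells, told apart by transcripts of Xist and of Y-linked genes, and the differences were not alike in the cells of each sex. Female cells made up 55.0% of kept oil cells and 60.9% of kept tamoxifen cells, and male cells 1362 and 1642 cells, or 27.8% and 21.8% of those given a sex. Alveolar macrophage-like cells were 4.47% of female oil cells and 27.2% of female tamoxifen cells (2.61), against 4.48% and 6.46% in male cells (0.53). ILC2-like cells were less frequent with tamoxifen in the cells of each sex, at 0.833% against 5.34% in female cells (-2.68) and 1.95% against 4.40% in male cells (-1.18). The T cell ratio over all subsets was 0.0093 in female (-0.071 to 0.089) and 0.48 in male cells, and among cells other than alveolar macrophages it was 0.40 (0.33 to 0.48) and 0.51 (0.35 to 0.67). The CD4 T ratio was 0.49 in female cells, or 0.89 without alveolar macrophages, and 2.76 in male cells, where it rested on 7 oil and 57 tamoxifen cells. Treg-like and cDC1-like cells went in opposite directions, with -1.20 and -1.02 in female cells and 1.95 and 0.51 in male cells, and without alveolar macrophages the female ratios were -0.81 and -0.63. CD8 T-like cells stood at -0.61 in female cells, or -0.22 (-0.54 to 0.10) without alveolar macrophages, and at 0.89 in male cells. No replicate allows a test of these differences between the sexes.

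**Figure D1:**
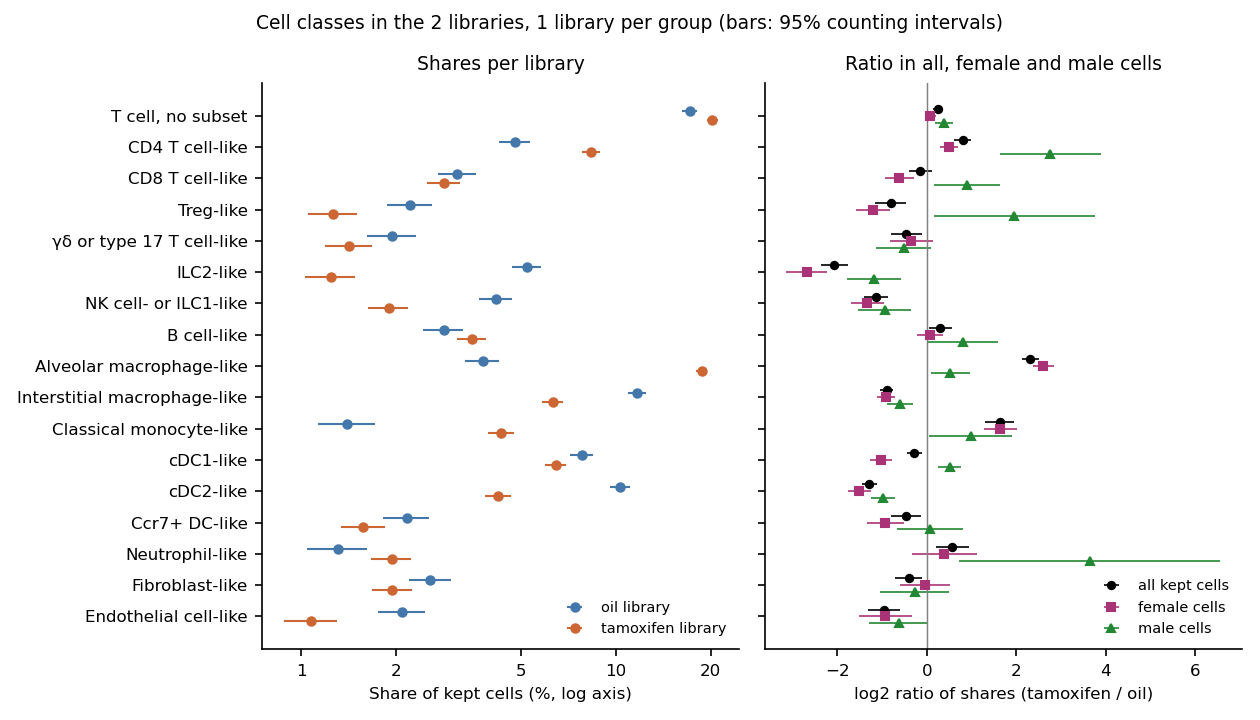
Share of kept cells in each class in the oil and tamoxifen libraries (left, percent on a log axis) and the log2 ratio of tamoxifen over oil for all, female and male cells (right), with bars for 95% counting intervals. Alveolar macrophage-like cells lie farthest to the right over all cells (2.32) and ILC2-like cells farthest to the left (-2.07).

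Summed Ifng transcripts were at the same level in the T, NK and ILC classes of both libraries. Ifng stood at 31.9 CPM in oil (434 UMIs) and 32.3 CPM in tamoxifen (610 UMIs), a log2 ratio of 0.02 (-0.16 to 0.20). At 1500 UMIs per cell, 78 of 2297 oil cells (3.40%, 2.69 to 4.22) and 92 of 3453 tamoxifen cells (2.66%, 2.15 to 3.26) had an Ifng UMI, -0.35 (-0.78 to 0.08). Without thinning 7.19% and 5.25% did, a lower share with tamoxifen beyond counting error. Thinning left out 178 oil and 145 tamoxifen cells that were too shallow. As background, an Ifng UMI was seen at 1500 UMIs per cell in 1 of 179 oil and 0 of 331 tamoxifen B-like cells, and in 1 of 241 and 0 of 1806 alveolar macrophage-like cells. Taken as 3 counts in place of 0, the tamoxifen cells allow up to 0.906% and 0.166%, less than an exact Clopper-Pearson limit would. Median depths were 5555 and 5095 UMIs in the T, NK and ILC classes and 6708.5 and 5993 in B-like cells. Within subsets, NK or ILC1-like cells carried more Ifng with tamoxifen (167 against 99.98 CPM, 0.74, 0.39 to 1.10) and CD8 T-like cells less (92.4 against 173 CPM, -0.90, -1.26 to -0.55). The thinned shares followed these directions, 18.1% against 9.13% in NK or ILC1-like cells and 7.75% against 13.1% in CD8 T-like cells, although at 1000 UMIs per cell the CD8 ratio was -0.17 (-1.03 to 0.69). Of CD8 T-like cells, the cluster with Ifng among its leading genes held 143 of 201 in oil and 133 of 274 in tamoxifen. Of NK or ILC1-like cells, the cluster led by Gzma and Klra4 held 56 of 266 in oil and 15 of 183 in tamoxifen. A UMI of the T cell receptor component Cd3g was found in 93 and 119 cells of this class. The mix of cells in this class thus differed, and its Ifng ratio was not separated from that mix. In CD4 T-like cells the share was 2.84% against 7.38%, with -0.22 for the summed UMIs (-0.56 to 0.12).

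Type 17 and inhibitory receptor transcripts were higher with tamoxifen in the T, NK and ILC classes summed, and type 2 and cytotoxic transcripts were lower. Of 10 type 17 genes, 9 were higher (median 0.19, 99.99th percentile of matched random lists). Il17a, which encodes a cytokine that recruits neutrophils, was at 1090 CPM against 420 CPM in oil (1.38, 1.34 to 1.42), Il17f at 135 against 46.3 CPM (1.55), and Il22, an epithelial barrier cytokine, at 36.8 against 16.1 CPM. At 1500 UMIs per cell an Il17a UMI was found in 12.9% of oil and 22.5% of tamoxifen cells of these classes, and in 1.81% of tamoxifen B-like cells. Of 9 genes in the inhibitory receptor list, not all of which encode receptors, 6 were higher (median 0.37, 99.99th percentile), among them Lag3 (43.5 against 8.61 CPM), Pdcd1 (207 against 131 CPM) and Cd200, a ligand that restrains myeloid cells (69.7 against 6.55 CPM, 3.41, 3.10 to 3.74). Of 14 type 2 genes, 12 were lower (median -0.82, 0th percentile), including Gata3 (89.1 against 158 CPM), the IL-33 receptor Il1rl1 (35.7 against 112 CPM), Arg1 (9.42 against 39.9 CPM) and Il9r (2.80 against 9.64 CPM). Of 17 type 1 effector and cytotoxic genes, 14 were lower (median -0.20, 0.01th percentile), led by granzyme A, Gzma (15.7 against 88.7 CPM), and with perforin, Prf1, at 16.4 against 33.2 CPM, and their median was -0.32 with cells thinned to 1500 UMIs. In T cells of no named subset, the largest of these classes, most type 1 genes were higher instead, as given under Other observations. Stx11, a syntaxin of granule secretion, was higher (103 against 37.8 CPM, 1.44), and Ptpn13 lower (22.8 against 56.3 CPM, -1.30).

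Part of these differences came from the mix of subsets. With the same mix of T, NK and ILC classes in both libraries, Cd200 stood at 2.74, Il17a at 0.96, Il17f at 0.98, Stx11 at 1.18 and Gzma at -1.74, whereas Il1rl1 stood at -0.24 and Ptpn13 at -0.45, and the medians became -0.39 for type 2, 0.07 for type 17 and 0.17 for inhibitory receptors. The mix was fixed by class only, so shifts between clusters within a class remain in these values. The CD4 T-like cluster led by Cd200, Il17f and Il17a held 90 oil and 509 tamoxifen cells, and the Gzma-led NK or ILC1-like cluster 56 and 15. In male cells Il17a did not differ (-0.01, against 1.58 in female cells), nor did the type 17 median (-0.02). The other lymphocyte programs lay close to 0 in the T, NK and ILC classes summed, although single subsets differed in some of them, as given below. Tissue residency had 6 of 12 genes higher (-0.00, 22.7th percentile), the IL-7 receptor and STAT5 list 7 of 14 (-0.01, 18.4th), with Il7r itself at 1617 and 1708 CPM, naive and recirculating genes 6 of 11 (0.12, within the middle 95% of random lists), interferon-gamma response genes 11 of 21 (0.01, 42.1th) and type I interferon genes 5 of 13 (-0.05, 31.0th). Cxcr6, a chemokine receptor of resident T cells, was found in 44.6% and 48.4% of thinned cells (1.12% and 1.51% of B-like cells), Itgae in 5.27% and 6.72%, Cd69 in 37.6% and 31.9%, close to the 30.2% and 33.5% of B-like cells, and Mki67 in 1.35% and 1.39%. The cycling list had 10 of 13 genes higher (0.24, 99.2th percentile), a median that was 0.03 with cells named one by one. Immediate early and dissociation genes were slightly lower (8 of 17 higher, -0.10, 0.095th percentile), and in male cells their median was 0.14. The lymphoid aggregate and germinal centre list had 4 of 6 genes higher (0.11, 79.1th percentile).

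Among single subsets, CD4 T-like cells showed the type 17 difference most fully. There 8 of 10 type 17 genes were higher (median 0.59, 100th percentile), with Il17a at 3701 against 1145 CPM and the decoy receptor Il1r2 at 159 against 27.6 CPM (2.53), while naive and recirculating genes were lower (8 of 10, -0.60) and type 2 genes as well (8 of 9, -0.86). Lilr4b (-2.22), St3gal6 (-1.90) and Serpina3g (-1.62) were lower and Cd200 (2.91) and Bdh2 (2.79) higher in these cells, of which the Il17a-led cluster held most in tamoxifen and the S1pr1-led cluster most in oil. CD8 T-like cells had 7 of 10 naive and recirculating genes higher (median 0.60, 100th percentile), such as Ccr7 and Dapl1 (2.08, or 2.21 relative to a median shift of -0.13 of all genes in this class). Hmgn1 (1.63), Serpina3g (1.77) and Epb41l4aos (1.70) were also higher and Slamf1 (-1.20), Tmem64 (-1.24), Il2 (-1.18) and Secisbp2l (-1.14) lower on that relative scale. A cluster led by Gzmk and Dapl1 held 58 oil and 141 tamoxifen CD8 T-like cells, and a cluster led by Ccr10 and Cd8a held 143 and 133. NK or ILC1-like cells had 14 of 16 type 1 and cytotoxic genes lower (-0.47, 0th percentile) and 13 of 17 interferon-gamma response genes higher (0.28, 99.9th). Gzma stood at 256 against 936 CPM (-1.87), Klra4 at -2.07, Irf8 at -1.72 and Klra3 at -2.48, with 40.9% of the Klra3 oil UMIs in 3 cells. The NK or ILC1-like cluster led by Gzma and Klra4 held 56 oil and 15 tamoxifen cells. T cell receptor components Cd3d (1.22) and Cd3g (1.02) were higher in this class. Gamma-delta or type 17 T-like cells carried more Areg, an epidermal growth factor receptor ligand linked to tissue repair (1412 against 172 CPM, 3.03, 2.77 to 3.31), with 3.31 in female and 2.20 in male cells. In tamoxifen 47 of these cells had an Areg UMI, and 3 of them held 36.45% of the UMIs.

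Alveolar macrophage-like cells of the tamoxifen library carried more interferon-response, inflammatory and sterol-synthesis transcripts and less of part of the lipid-handling program. Of 22 interferon-gamma response genes, 18 were higher (median 0.49, 100th percentile), including the T cell-attracting chemokines Cxcl9 (56.1 against 22.8 CPM) and Cxcl10 (18.6 against 6.68 CPM), and Gbp5 (16.6 against 5.97 CPM). Of 12 inflammatory genes, 8 were higher (median 0.33, 100th percentile), with Tnf at 118 against 45.7 CPM (1.37), Il1b at 413 against 193 CPM and the neutrophil chemoattractant Cxcl2 at 1052 against 729 CPM, whereas Ccl3 (203 against 362 CPM) and Ccl4 (97.96 against 138 CPM) were lower. Cholesterol synthesis genes were higher as a group, 11 of 13 (median 0.60, 100th percentile), among them Hmgcs1 (0.96) and Idi1 (0.95). MHC class II genes were higher in 9 of 10 cases (median 0.44, 99.98th). Of 13 lipid-handling genes 11 were lower (median -0.22, 0th percentile), chiefly the fatty acid-binding proteins Fabp4 (209 against 485 CPM, -1.21) and Fabp5 (389 against 803 CPM, -1.05), the scavenger receptor Cd36 (234 against 452 CPM) and the cholesterol exporter Abca1 (77.1 against 177 CPM, -1.20), while Pparg and Lpl were close to equal (-0.11 and 0.03).

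Other alveolar macrophage genes that were higher with tamoxifen were Ereg, an epidermal growth factor receptor ligand (63.7 against 10.5 CPM, 2.59), Nov (2.62), Cxcl3 (1.46), Tgfbi (1.13), Fpr1 (1.02) and Camk1d (1.06). Fstl1, a secreted glycoprotein of the follistatin family, was far lower (3.94 against 99.1 CPM, -4.65, -5.04 to -4.28), as were Gpnmb (-1.42), Rgcc (-1.32) and the growth factor Igf1 (51.2 against 121 CPM, -1.24). The macrophage marker Chil3 stood at 8807 against 14270 CPM, and of 9 alternative activation genes 7 were lower (-0.05, 14.9th percentile). Matrix protease genes were mixed (6 of 10 higher, 0.16, 92.7th), with Mmp8 at 17.2 against 6.68 CPM and Ctsk at 316 against 463 CPM. The type I interferon list stood at 1.67 (11 of 12 higher), but Ifi44 had no UMI in oil and 5 of the 12 genes had 3 or fewer there. With Ifi44 set to the limit of 3 counts the median was 0.97, and with cells thinned to 1500 UMIs it was -0.56. Ifi27l2a was its best-measured member (92.2 against 18.3 CPM, 2.34, 1.94 to 2.76). The sex mix of this class differed, with 158 female and 61 male oil cells and 1602 and 106 tamoxifen cells. Of the 8 named higher genes 6 were also higher in male cells, not Ereg (-0.43) and Camk1d (-0.02), and of the 6 Tnf (0.25, -0.35 to 0.87) and Fpr1 (0.39, -0.14 to 0.94) lay within counting error there, but of the 8 lower ones only Gt(ROSA)26Sor and Abca1 were lower there, and Fabp4 (0.40), Fabp5 (1.54) and the lipid-handling median (0.05) went the other way. Fstl1 had 0 oil and 61 tamoxifen UMIs in male cells and 263 and 13 in female cells. A small cluster of this class led by Inhba, Cxcl3, Ctsk and Fstl1 held 18 oil and 79 tamoxifen cells. Without doublet removal the MHC class II median of this class was -0.51 and its inflammatory median 0.52, in male cells the inflammatory median was 0.082, and with cells thinned to 1500 UMIs the cholesterol median was 0.96, with 0.37 in female and 1.23 in male cells.

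B-like cells showed the interferon-gamma response across every measured gene of the list. All 18 were higher with tamoxifen (median 1.02, 100th percentile), with Gbp7 at 74.4 against 28.6 CPM (1.38), the feedback inhibitor Socs1 at 66.6 against 28.6 CPM (1.22), Irf1 at 102 against 53.7 CPM and Irgm1 at 39.2 against 12.5 CPM. In male B-like cells the median was 0.53. MHC class II genes of B-like cells did not stand apart (7 of 10 higher, 0.07, 74.9th percentile), nor did the lymphoid aggregate list (6 of 7 higher, 0.06, 67.2th). Asph (-1.13) and St3gal6 (-1.01) were lower. Tppp3 stood at -1.17, with 42.1% of its UMIs in 3 cells, and at -0.40 (-0.93 to 0.14) in female cells.

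Interstitial macrophage-like cells went the other way from alveolar macrophages in several programs. Of 10 MHC class II genes 9 were lower (median -0.34, 0th percentile), with H2-Aa at 10730 against 13530 CPM, while H2-Eb1 was higher (6249 against 4586 CPM). All 9 measured type I interferon genes were lower (-0.31, 1.15th percentile), 13 of 20 interferon-gamma response genes (-0.12, 2.31th) and 10 of 14 inflammatory genes (-0.16, 0.25th), for example Ccl4 at 745 against 1148 CPM and Cxcl10 at 46.7 against 87.8 CPM. With cells named one by one the 2 interferon medians were 1.26 and 0.67, and in male cells the MHC class II and inflammatory medians were 0.10 and 0.10. Alternative activation genes (8 of 13 higher, 0.07, 67.1th percentile) and matrix proteases (9 of 12 higher, 0.14, 90.3th) stayed near the middle of random lists. The lectin Clec10a was higher (61.0 against 29.9 CPM, 1.03), whereas the higher Ctsk and Acp5 and the lower Lyz1 came mostly from a few cells, with 98.05%, 62.15% and 86.7% of their UMIs in 3 cells.

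**Figure D2:**
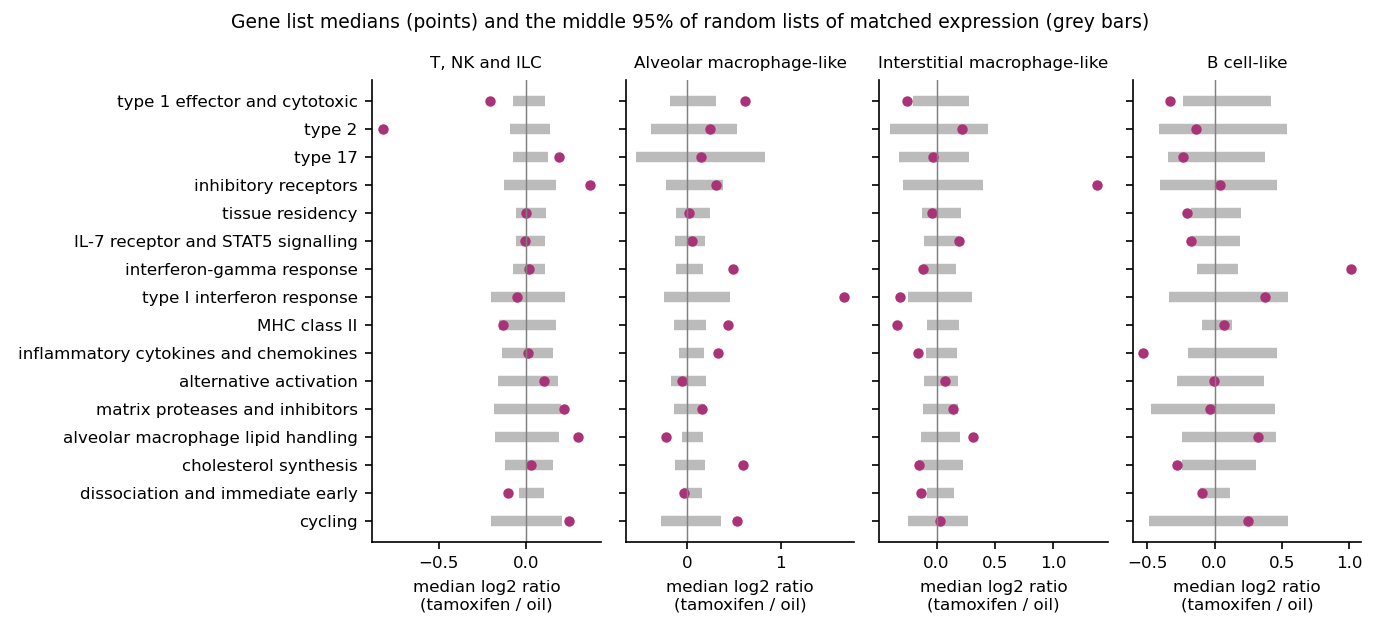
Median log2 ratio of tamoxifen over oil (points) for 16 gene lists in the T, NK and ILC classes, alveolar macrophages, interstitial macrophages and B cells, with grey bars for the middle 95% of 10000 random lists matched on expression. The interferon-gamma response lies to the right of its bar in alveolar macrophages (0.49) and B cells (1.02) and close to 0 in the T, NK and ILC classes (0.01).

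Dendritic, endothelial and fibroblast-like cells added further differences. In Ccr7-positive dendritic cells all 10 MHC class II genes were higher (median 0.83, 100th percentile) and 11 of 13 inflammatory genes lower (-0.55, 0th), with Tm4sf5 at 272 against 99.6 CPM (1.45) and Apol7c at 410 against 976 CPM (-1.25). Upb1 (-2.62) and Plk2 (-1.68) were also lower, and Bcl2l14 (1.29) and Dnajc21 (1.08) higher. Of the Plk2 oil UMIs 41.55% lay in 3 cells, and its ratio in male cells was -0.35 (-1.47 to 0.76). cDC1-like cells had H2-Eb1 at 6541 against 3006 CPM (1.12, 1.10 to 1.15, with 0.49 in female and 0.99 in male cells) and 12 of 13 cholesterol synthesis genes lower (-0.42, 0th percentile), while cDC2-like cells had the lectin Asgr2 at 434 against 189 CPM (1.20) and the monocyte-attracting chemokines Ccl7 (36.0 against 109 CPM, -1.59) and Ccl2 (181 against 392 CPM, -1.11) lower. Apol7c and Asgr2 are themselves among the genes that lead the clusters of these classes. Endothelial-like cells had all 7 measured MHC class II genes higher (1.17, 100th percentile) and Cyp26b1, which degrades retinoic acid, at 49.6 against 1100 CPM (-4.47, -5.06 to -3.94). Their apparently higher Fabp4, Selp and Cpe came mostly from 3 cells (96.0%, 83.1% and 63.8% of UMIs).

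Outside the immune programs, 2 neighbouring genes were lower in the tamoxifen library in every class examined. Setd5 (ENSMUSG00000034269, GRCm38 chromosome 6, 113077365 to 113153435) encodes a SET-domain protein and stood at 43.8 against 108 CPM over all kept cells (-1.30, -1.37 to -1.24). It was lower in 15 of 15 classes, in 14 of them beyond counting error. Gt(ROSA)26Sor (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333, minus strand), the non-coding transcript of the Rosa26 locus, which is widely used to insert transgenes, stood at 24.5 against 57.2 CPM (-1.22, -1.31 to -1.14) and was lower in 15 of 15 classes, in 13 of them beyond counting error. It overlaps the end of Thumpd3 on the other strand, so its counts are less certain, and Thumpd3 itself differed little (0.12). The ratios of Setd5 were -1.25 in female and -1.53 in male cells. Over the other 16 measured genes within 500 kb the median was 0.09. Of the sex-linked genes, Xist was at 628 and 632 CPM (0.01) and Ddx3y at 40.6 and 32.3 CPM (-0.33), and all 6 were lower in the T, NK and ILC classes (-0.11, 8.63th percentile). In alveolar macrophage-like cells 5 of 6 were lower (-1.56, 0th percentile).

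**Figure D3:**
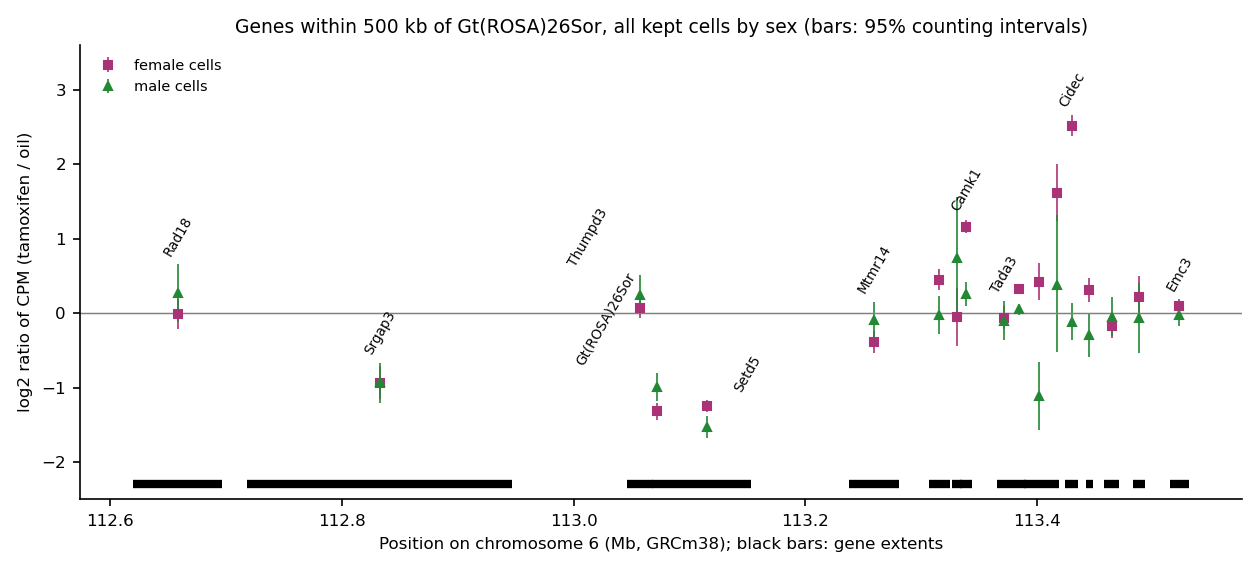
Log2 ratio of tamoxifen over oil for genes within 500 kb of Gt(ROSA)26Sor against position on chromosome 6 (megabases, GRCm38), in female and male cells, with bars for 95% counting intervals and black bars for gene extents. Setd5 (-1.25 and -1.53) and Gt(ROSA)26Sor (-1.32 and -0.99) lie below the other genes in female cells, and in male cells Ttll3 (-1.11) and Srgap3 (-0.93) lie at a level similar to Gt(ROSA)26Sor.

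Transcripts of other cell types also differed between the libraries. Haemoglobin genes were higher in the T, NK and ILC classes (4 of 4, median 0.51), where 8 tamoxifen cells held 13421 of 13845 UMIs and 5 oil cells 6724 of 7089. In the other cells of these classes they were at 22.4 against 26.9 CPM. The haemoglobin medians were 2.75 in alveolar macrophages, where 1 tamoxifen cell held 2006 of 2215 UMIs, and 5.60 in CD4 T-like cells, where 5 tamoxifen cells held 9152 of 9250. Of 3 measured epithelial genes in these classes 2 were higher (0.75, 97.4th percentile), with Sftpc at 6.88 against 1.25 CPM, and the club cell gene Scgb1a1 was lower, at 4.92 against 42.2 CPM. In the T, NK and ILC classes the macrophage lists also sat above 0, with alveolar macrophage lipid handling at 0.30 (99.8th percentile), matrix proteases at 0.22 (98.1th), alternative activation at 0.10, cholesterol synthesis at 0.03 (53.9th) and inflammatory genes at 0.01 (43.9th), and MHC class II genes lay at -0.13 (4.96th).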

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

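The tests in this part were chosen after the results were seen, except that lymphoid cells as denominator and median-of-ratios scaling were among the alternatives set beforehand. Several ratios of tamoxifen over oil had opposite signs in female and male cells, and these differences between the sexes were not tested. For shares of cells, female minus male log2 ratios were -0.45 for the T, NK and ILC classes summed (-0.23 in female, 0.22 in male cells), -1.50 for CD8 T-like cells (-0.61 and 0.89), -3.16 for Treg-like cells (-1.20 and 1.95, with 3 male oil cells and 14 male tamoxifen cells) and -1.53 for cDC1-like cells (-1.02 and 0.51). Without alveolar macrophages in the denominator, the T, NK and ILC classes had the same sign in both sexes (0.16, 0.10 to 0.23, in female and 0.25, 0.12 to 0.39, in male cells), and the female ratio of CD8 T-like cells lay within counting error (-0.22, -0.54 to 0.10). In alveolar macrophage-like cells they were -1.83 for Fabp4 (-1.43 and 0.40) and -2.93 for Fabp5 (-1.39 and 1.54). For Fstl1 in the same class the difference was -10.8, where the male value of 3.36 is a bound because no oil UMI was found. In interstitial macrophage-like cells it was -4.01 for Lyz1 (-2.43 and 1.57), of which 3 cells held 86.7% of UMIs.

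Alveolar macrophage-like cells were a larger share of the tamoxifen library (log2 ratio 2.32). A mitochondrial limit of 25% left the ratio at 2.37, which argues against their loss from the oil library through that limit. Counting the low-UMI cluster led by Fabp1 with them raised the cells from 242 to 452 in oil and from 1812 to 2211 in tamoxifen. The ratio then fell to 1.70 (1.56 to 1.84), so cells left unnamed could account for part of the difference but not all of it. Without that cluster the ratio was 2.61 in female and 0.53 in male cells, 2.08 apart, but with 1 library per group this does not decide whether animals of 1 sex carried the difference. The deletion of Hhip, differences between single animals and differences in how many airspace cells were recovered remain open as untested, since each group is 1 library.

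ILC2-like cells were a smaller share of the tamoxifen library (-2.07). Among barcodes with 10% to 25% mitochondrial UMIs, ILC2-like ones were 436 of 1855 in oil (23.5%) and 111 of 1556 in tamoxifen (7.13%). These shares exceed the 5.20% and 1.24% of kept cells, so the limit took many ILC2-like barcodes from both libraries. The ratio among them was -1.72 (upper bound -1.44), which argues against a loss mainly from the tamoxifen library. Among lymphoid cells alone the ratio was -2.04, which argues against dilution by alveolar macrophages. In male cells, the sex with the smaller difference, it was -1.18, so the lower share was seen in the cells of each sex. An effect of the deletion is a candidate explanation, and differences between the animals or the preparations of the libraries were not tested.

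Setd5 and Gt(ROSA)26Sor were lower in the tamoxifen library in all 15 classes (-1.30 and -1.22 over kept cells). The largest median shift of all genes in any class was -0.13, too small for scaling to be the source, and of the other 16 genes within 500 kb only Srgap3 (-0.93), or 6.25% (0.158 to 30.2), was lower by at least 1/2 of the Setd5 ratio, which argues against the wider region being lower. Setd5 was lower beyond counting error in 14 classes, immune and endothelial, but not in fibroblast-like cells (-0.42, -0.90 to 0.05). Gt(ROSA)26Sor lay within counting error in fibroblast-like cells (-0.21, -0.87 to 0.46) and in B-like cells (-0.31, -0.79 to 0.18). The lower values might reflect animals that differed at the locus. Transgenes are often inserted at Rosa26, but genotype there is not in the labels and would be confounded with the groups, so it cannot be told apart from an effect of the treatment.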

How the results depend on the processing

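Alternatives with cells of 1 sex, a mitochondrial limit of 25%, denominators without alveolar macrophages, the low-UMI cluster with Fabp1 and a fixed mix of T, NK and ILC classes were chosen after seeing the data. Log2 ratios of class shares kept their direction in 173 of 177 values under alternatives set beforehand and in 65 of 71 under those added later, list medians in 165 of 186 and 54 of 73, and gene ratios in 591 of 593 and 215 of 235, where 3 of the other 20 are bounds that exclude neither direction. The share of alveolar macrophage-like cells ranged from 1.49 to 2.46 under the former and from 0.53 to 2.61 under the latter, and that of ILC2-like cells from -2.10 to -1.69 and from -2.68 to -1.18. Class shares and list medians that went beyond their interval follow by alternative, and the cause was not tested. Values that changed sign within their interval are only in the counts above. Of single genes only changed signs follow, since 115 gene ratios moved beyond their interval in the same direction under the alternatives set beforehand and 101 under those added later. Each library clustered alone gave no classical monocyte class, and a gene minimum of 200 no plasma cell class. Depth limits genes such as Hhip, Gli1 and the ligand genes, most type I interferon genes in alveolar macrophages, and classes with few male cells. No paired analysis was possible because each group had 1 library.

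In male cells alone, share ratios changed sign for Treg (1.95), cDC1 (0.51), Ccr7-positive dendritic cells (0.074) and CD8 T (0.89), and stood at 0.48 for all T cells, 0.39 for T cells of no subset, 2.76 for CD4 T, -1.18 for ILC2, 0.80 for B cells, 0.53 for alveolar macrophages, -0.60 for interstitial macrophages, 0.98 for monocytes, -0.98 for cDC2 and 3.64 for neutrophils. Genes with a value of the other sign in male cells, within counting error there except for Fstl1, Fabp4 and Fabp5 in alveolar macrophages and Lyz1, were, in the T, NK and ILC classes, Il17a (-0.0057) and Rnaset2b (-0.15), and in alveolar macrophages Ereg (-0.43), Camk1d (-0.023), Fstl1 (3.36, a bound), Gpnmb (0.22), Rgcc (0.30), Fabp4 (0.40), Igf1 (0.16) and Fabp5 (1.54). Others were Cd200 (-0.998) and Rnaset2b (-0.78) in CD4 T, Dapl1 (-0.082, a lower bound that shows no reversal) in CD8 T, Lyz1 (1.57) in interstitial macrophages and Rnaset2b (-0.13) in T cells of no subset. In Treg they were Satb1 (-1.67) and Churc1 (-0.081), each with 1 oil UMI, and Rnaset2b (-1.38) and Pclaf (-1.84), whose values are lower bounds that show no reversal because no oil UMI was found. List medians that changed sign in male cells were type 17 (-0.019), immediate early (0.14), naive (-0.045), IL-7 receptor and STAT5 (0.14) and lymphoid aggregate genes (-0.26) in the T, NK and ILC classes, lipid handling in alveolar macrophages (0.048), and MHC class II (0.10) and inflammatory genes (0.10) in interstitial macrophages. In the T, NK and ILC classes type 2 was at -0.37 and interferon-gamma response at 0.26. In alveolar macrophages they were MHC class II 2.32, inflammatory 0.082, matrix proteases 0.45, cholesterol synthesis 1.23 and immediate early -0.25. In B cells they were interferon-gamma response 0.53 and MHC class II 0.32, and in interstitial macrophages type I interferon -0.026 and alternative activation 0.67.

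In female cells alone, Sftpa1 in fibroblasts, with 3 UMIs in each library, changed sign (-0.68), as did the matrix protease (-0.23) and immediate early (0.13) medians of alveolar macrophages and the alternative activation median of interstitial macrophages (-0.29). Share ratios were 0.0093 for all T cells, 0.075 for T cells of no subset, 0.49 for CD4 T, -0.61 for CD8 T, -1.20 for Treg, -2.68 for ILC2, 2.61 for alveolar macrophages, -1.02 for cDC1 and -1.50 for cDC2. Medians were -0.45 for type 1 and 0.30 for type 17 genes in the T, NK and ILC classes. In alveolar macrophages they were 2.08 for type I interferon, 0.71 for MHC class II and 0.37 for cholesterol synthesis. In interstitial macrophages the MHC class II median was -0.61.

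With cells named one by one, signs changed for the gamma-delta or type 17 share (0.12), for Pclaf (-0.22) and Tnfsf8 (0.45) in Treg, for interferon-gamma (0.67) and type I interferon (1.26) responses in interstitial macrophages, for type I interferon in the T, NK and ILC classes (0.57) and for matrix proteases in alveolar macrophages (-0.25). Shares were 0.10 for all T cells, 0.14 for T cells of no subset, 0.26 for CD4 T, -0.28 for Treg, -1.69 for ILC2, 2.10 for alveolar macrophages and -0.54 for interstitial macrophages. Medians were 0.029 for cycling in the T, NK and ILC classes, -0.65 for alternative activation in alveolar macrophages, and 0.20 for MHC class II in B cells. In interstitial macrophages they were -0.30 for inflammatory, 0.23 for alternative activation, 0.49 for matrix proteases and -0.26 for immediate early genes.

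With cells thinned to 1500 UMIs, signs changed for the type I interferon (-0.56) and matrix protease (-0.17) medians of alveolar macrophages and the MHC class II median of B cells (-0.076). Medians were -0.32 for type 1 and -1.005 for type 2 in the T, NK and ILC classes, 0.33 for interferon-gamma response and 0.96 for cholesterol synthesis in alveolar macrophages, and -0.34 for interferon-gamma response in interstitial macrophages. Without doublet removal the MHC class II median of alveolar macrophages changed sign (-0.51), and their medians were 0.31 for interferon-gamma response, 0.71 for type I interferon, 0.52 for inflammatory genes, -0.45 for alternative activation and 0.84 for cholesterol synthesis. Shares were then 0.62 for CD4 T, 0.20 for CD8 T (a changed sign), 1.67 for alveolar macrophages and -0.75 for interstitial macrophages.

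With each library clustered alone, shares were 0.10 for all T cells, 0.38 for T cells of no subset, 0.29 for CD4 T, -1.22 for gamma-delta or type 17 T, 1.49 for alveolar macrophages, -1.32 for interstitial macrophages and -1.01 for cDC2. Among kept cells without alveolar macrophages they were 0.47 for all T cells, 0.49 for T cells of no subset, 1.05 for CD4 T, -0.65 for interstitial macrophages, -0.035 for cDC1 and -1.04 for cDC2, and among myeloid cells -1.07 for interstitial macrophages, -0.46 for cDC1 and -1.46 for cDC2. The CD4 T share was 0.55 with a mitochondrial limit of 5%, 1.06 with a limit of 25% and 0.53 with a gene minimum of 500, and the CD8 T share 0.14, a changed sign, with the limit of 25%. The alveolar macrophage share was 2.07 with a gene minimum of 200, 2.10 at Leiden resolution 2 and 1.70 with the low-UMI cluster, and at resolution 2 interstitial macrophages were at -0.58 and cDC2 at -1.46.

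With a mitochondrial limit of 5%, medians were 0.037 for cycling in the T, NK and ILC classes, and 0.66 for MHC class II, 0.66 for inflammatory and -0.16 for immediate early genes in alveolar macrophages. With at least 100 UMIs per member, type I interferon (0.45) and alternative activation (-0.37) moved in alveolar macrophages. With the same mix of T, NK and ILC classes, the type 2 median was -0.39, type 17 0.072 and inhibitory receptors 0.17.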

Other observations

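Smaller classes held further differences. In ILC2-like cells, Il5, which encodes the eosinophil growth factor and is a marker used to name the class, stood at 486 CPM with tamoxifen against 74.2 CPM in oil, while Gata3 (567 against 539 CPM) and Il1rl1 (687 against 662 CPM) were close to equal and 7 of 12 type 2 genes were lower (median -0.16, 3.32th percentile). Lif (11.6 against 69.4 CPM, -2.58, 45.5% of oil UMIs in 3 cells) and the hormone-processing protease Pcsk1 (34.7 against 143 CPM, -2.04) were lower there, and 14 of 17 immediate early genes higher (0.39, 100th percentile). The higher mast cell protease genes Mcpt4, Cma1 and Tpsb2 of this class lay in 1 cell. In Treg-like cells Satb1 was higher (2.13, 38.2% of tamoxifen UMIs in 3 cells) and Ttn lower (-1.70), and Tnfsf8 was lower (-2.17) with 65.5% of its UMIs in 3 cells. In gamma-delta or type 17 T-like cells Pex3 (2.11) and Sgip1 (1.45, 44.3% of tamoxifen UMIs in 3 cells) were higher and Espn (-1.65) lower. T cells of no named subset had 10 of 13 type 1 genes higher (0.23, 99.8th percentile).

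Fibroblast-like cells of the tamoxifen library carried more inflammatory transcripts, with 10 of 11 genes higher (median 0.82, 100th percentile), among them the neutrophil chemoattractants Cxcl1 (719 against 175 CPM) and Cxcl2 (408 against 71.7 CPM) and the prostaglandin synthase Ptgs2 (135 against 24.3 CPM). The same cells held T cell transcripts, with 123 UMIs of Il17f against 0 in oil (at least 33.0-fold higher), and epithelial transcripts at a median of 6.16, or 5.83 with genes at 0 set to their bound. In 3 cells lay 98.7% of Sftpc UMIs. The Il17f UMIs lay in 13 tamoxifen cells, and 3 of these cells held 68.3% of them. Members of the inflammatory list were not screened for free RNA. In Ccr7-positive dendritic cells the chemokine Ccl1 had 0 UMIs in oil and 145 in tamoxifen, all in 3 cells (at least 45.5-fold higher). Endothelial-like cells had 5 of 6 inflammatory genes higher (1.56).

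Genes of 2 other places in the genome differed across classes and were chosen after their values were seen. On GRCm38 chromosome 17, Rnaset2b (6970634 to 7011299) was higher in 15 of 15 classes (0.92 over kept cells, 2.93 in female and -0.23 in male cells) and Rnaset2a (8115445 to 8148097) lower in 14 of 15 (-0.76). These paralogs are nearly identical, so the assignment of reads between them is uncertain. Sft2d1 (chromosome 17, 8311102 to 8327442) was higher in 15 of 15 classes (0.83, 1.82 in female and -0.05 in male cells). Samd11 (chromosome 4, 156246966 to 156255657) was lower in 13 of 15 classes (-1.35, -1.11 in female and -2.89 in male cells).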
